A study of Rattus norvegicus with 12 samples.

How the data were processed

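The series holds 12 CUT&Tag libraries from primary vascular smooth muscle cells of Rattus norvegicus: 3 histone marks (H3K23ac, H3K27ac and H4K5ac), each in 2 conditions (NC and SIANK) with 2 libraries each. Per the labels' protocols, cells were bound to concanavalin A beads, incubated with an antibody to the mark or with normal IgG, and cut with a protein A/G transposase from a commercial kit. IgG libraries were not analysed here. Groups came from the treatment label of each sample and replicate numbers from its title.

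The authors deposited 1 peak list per library, so peaks were called library by library in the files used here. Per the file headers, each list gives the chromosome, start, end and length of each peak; the length equals end minus start plus 1 in every entry, so positions count from 1. The deposited lists hold no height, score, fold enrichment or p-value per peak and no read count. The submitters' processing notes name BWA and deepTools, without versions or roles. The peak caller, its threshold, any control and the genome build are not given in the sources used here. A longer list can come from deeper sequencing, a higher signal over background or a looser threshold as well as from more marked regions, and no value in the lists tells these apart. Lists held chromosomes 1 to 20, X and Y.

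The only annotation at hand was a table of genes on GRCr8, and the peaks were not on that assembly: 2696 peaks on 15 chromosomes lay beyond the last GRCr8 gene, and the percent of peaks of H3K27ac SIANK library 2 within 1 kb of a gene end was 5.58 at the positions as given against 5.89 to 5.95 when shifted by 100000 or 1000000 bp. No coordinates were converted and no gene names are given. The planned results at promoters and for 16 gene lists were not run, and regions stand in their place, named by position.

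Peaks of the 4 libraries of a mark were merged into regions where they overlapped by at least 1 bp. A region was gained when both SIANK libraries and neither NC library had a peak in it, and lost in the reverse case. The named regions followed a rule fixed before the data were examined: for each mark, up to 10 gained and 10 lost regions and 5 regions of all 4 libraries, ranked by the lowest within-library percentile of peak length in the libraries that had them, since no score was given. The text gives some of these in full and the rest as counts. Lost regions of H4K5ac numbered 2, so both are named. The number of peaks and the covered length per library were compared on the log2 scale by exact two-sided permutation of condition labels within each mark (6 arrangements, smallest p 0.333) and over the 3 marks (216 arrangements, smallest p 0.00926); the threshold was 0.05. Differences between marks used 36 arrangements (smallest p 0.0556). Gained and lost counts were set beside the same counts for the other pairings of the 4 libraries and carry no p. Overlaps between marks were compared with 1000 circular shifts of the regions within their chromosomes, whose smallest p is 0.001, and overlaps of gained regions with Fisher's exact test on the merged regions of the 3 marks, adjusted by Benjamini-Hochberg over the 6 tests of a background (3 pairs of marks, gained and lost). Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over regions only. The peak length at shared regions, the percent overlap of regions between marks and the overlaps of gained regions were chosen after the files had been seen.

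Alternatives were covered length in place of peak number, merging within 1000 bp, peaks at or above the median length of a mark's pooled lists, the upper 50% of each list by length, lists of equal length, coverage of at least 50% of a region, a block by replicate number, leaving out H4K5ac, and leaving out each library in turn, where 1 library then stands for its condition. Merging was checked against bedtools 2.31.1 and gave identical regions (21414, 17378 and 1850). On simulated lists with the sizes and peak lengths of the real ones, 100% of 200 gained, 100 lost and 200 shared regions were recovered for each mark. Simulated regions and other peaks were placed apart, so this checks the counting only. It does not measure false gained or lost calls. The stratified permutation test called 6% of 200 simulated sets without a shift and 100% of 200 sets with a log2 shift of 2. The simulated spread was equal for all marks and smaller than that seen for H3K27ac and H4K5ac. These rates therefore do not give the power of the test in these data. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.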

Results

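Histone acetylation was profiled by CUT&Tag in primary rat vascular smooth muscle cells (VSMCs), the contractile cells of the arterial wall. In CUT&Tag an antibody bound to a chromatin mark tethers a transposase, which cuts and tags the DNA next to that mark. The series addresses which parts of the genome carry 3 marks in VSMCs, in work on aneurysmal aortas. The marks are acetylation of lysine 23 of histone H3 (H3K23ac), of lysine 27 of histone H3 (H3K27ac, a mark of active enhancers and promoters) and of lysine 5 of histone H4 (H4K5ac). For each mark there were 2 libraries of the condition labelled NC and 2 of the condition labelled SIANK, a label that the sources used here do not spell out. The 12 libraries gave 12 peak lists with 94690 peaks in all. The lists hold positions and lengths and no read counts, so the sequencing depth behind them is unknown. Nothing in the labels says whether replicates came from separate cultures or animals. The permutation tests of condition labels therefore measure only the spread between these libraries, which may be technical. Fisher's exact tests, the circular shifts and the intervals on region counts treat regions as units and do not measure that spread.

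The 3 marks differed in how much of the genome their lists covered. H3K23ac had 12909 and 10720 peaks in NC libraries 1 and 2, covering 11.3 and 9.94 Mb. H3K27ac had 2644 and 14034 peaks, covering 1.87 and 13.5 Mb, so its NC replicates lay far apart. H4K5ac had 100 and 371 peaks, covering 0.0449 and 0.184 Mb. Peaks were also shortest for H4K5ac, with median lengths of 405 and 427 bp in the NC libraries against 711 and 765 bp for H3K23ac and 607.5 and 790.0 bp for H3K27ac. Peaks of at least 5 kb occurred for H3K23ac (17 and 14 in the NC libraries, 17 and 46 in the SIANK libraries) and for H3K27ac (0 and 24, then 2 and 32). None was listed for H4K5ac in any of its 4 libraries.

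SIANK libraries held more H3K23ac and H4K5ac peaks than NC libraries in every comparison of single libraries. For H3K23ac, SIANK libraries 1 and 2 had 14356 and 17141 peaks, and the group means were 15748.5 ± 1969 against 11814.5 ± 1548 in NC (SD, n = 2 each). For H4K5ac, the SIANK libraries had 468 and 1711 peaks, with means of 1089.5 ± 879 against 235.5 ± 192 (SD, n = 2 each). For H3K27ac, the SIANK libraries had 4823 and 15413 peaks, with means of 10118 ± 7488 against 8339 ± 8054 (SD, n = 2 each), a difference far inside the spread. The SIANK over NC ratio of geometric means was 1.33 for H3K23ac (log2 0.42, SE 0.19), 1.42 for H3K27ac (log2 0.50, SE 1.47) and 4.65 for H4K5ac (log2 2.22, SE 1.33). Exact two-sided permutation tests within a mark gave p = 0.333, 0.667 and 0.333, where 0.333 is the smallest p that 2 libraries against 2 can give. Over the 3 marks together the ratio was 2.06 (log2 1.04), and the exact permutation test stratified by mark gave p = 0.120, with a smallest possible p of 0.00926. In this unpaired test, which takes the marks as independent, the difference over the 3 marks did not pass the threshold of 0.05. Without NC 1, NC 2, SIANK 1 and SIANK 2 of each mark in turn, the log2 ratio over the 3 marks was 0.37, 1.72, 1.68 and 0.41 and that of H4K5ac was 1.27, 3.16, 3.15 and 1.28, and without H4K5ac the log2 ratio over the other marks was 0.46. Differences in ratio between marks had exact permutation p between 0.556 and 0.944, but the smallest p this design allows is 0.0556, so it could not show that marks differ.

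Replicate number separated the H3K27ac lists more than condition did. Within number 1, SIANK had 1.82 times as many H3K27ac peaks as NC, and within number 2 it had 1.10 times as many. The same ratios were 1.11 and 1.60 for H3K23ac, and 4.68 and 4.61 for H4K5ac. Leaving out NC library 1 of each mark turned the pooled H3K27ac log2 ratio from 0.50 to −0.70, and leaving out SIANK library 2 turned it to −0.34.

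**Figure D1:**
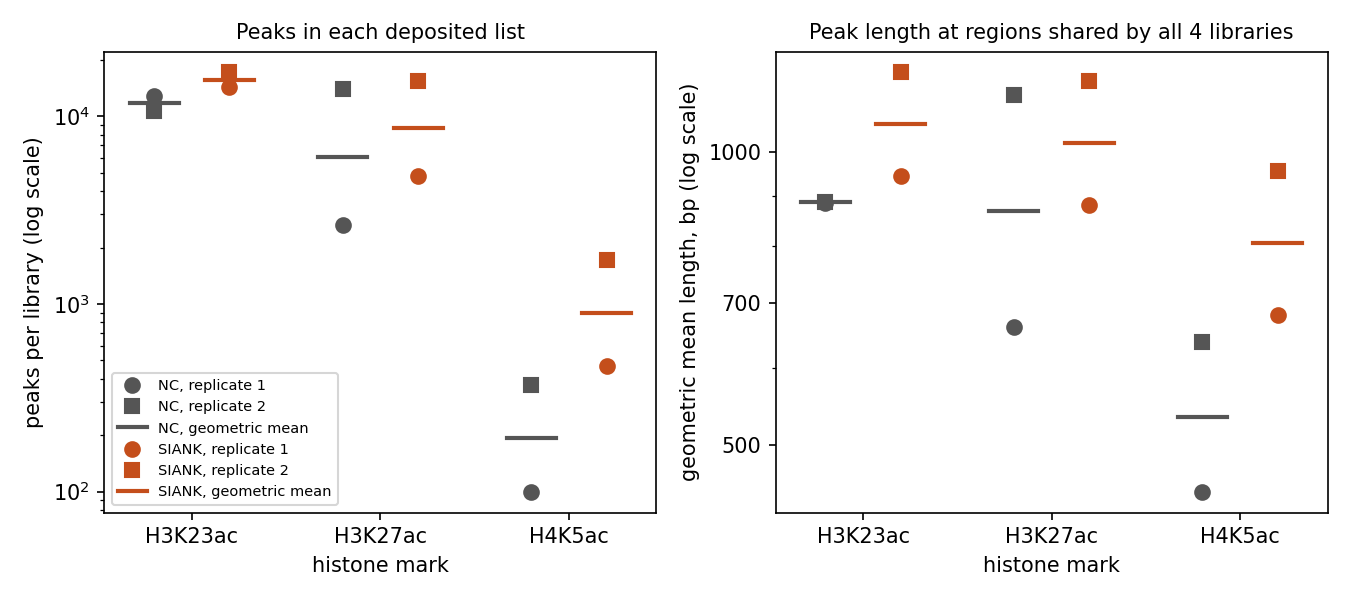
Number of peaks in each of the 12 lists (left, log axis) and geometric mean peak length in bp at regions with a single peak in each of the 4 libraries of a mark (right, log axis); circles are replicate 1, squares replicate 2, and bars the geometric mean of a condition. H4K5ac ran from 100 to 1711 peaks and H3K27ac from 2644 to 15413, with the number 2 libraries higher in both conditions.

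Peaks found in every library of a mark were longer in the SIANK lists for H3K23ac and H4K5ac. At 6342 H3K23ac regions with exactly 1 peak in each of the 4 libraries, the geometric mean peak length was 887 and 888 bp in NC and 945 and 1206 bp in SIANK, a log2 ratio of 0.27 (SE 0.18). At 64 such H4K5ac regions it was 448 and 638 bp in NC and 680 and 956 bp in SIANK, a log2 ratio of 0.59 (SE 0.35). At 1998 such H3K27ac regions it was 661 and 1144 bp in NC and 881 and 1184 bp in SIANK, a log2 ratio of 0.23 (SE 0.45) that again lay inside the difference between the NC replicates. Over the 3 marks the ratio was 1.29 (log2 0.36), with p = 0.0648 in the exact two-sided permutation test stratified by mark. Without NC 1, NC 2, SIANK 1 and SIANK 2 of each mark in turn the log2 ratio was 0.15, 0.58, 0.58 and 0.15, and without H4K5ac it was 0.25. This measure was added after the peak counts had been seen.

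By count, H3K23ac was the mark with the most regions found in both SIANK libraries and in neither NC library. Merging the peaks of its 4 libraries gave 21414 regions, of which 1572 were gained in this sense and 20 were lost, meaning found in both NC libraries and in neither SIANK library. The gained regions had a median length of 767 bp, against 1481.5 bp for the 7420 regions found in all 4 libraries. By peak length within its libraries, the top gained region lay on chromosome 20 from 7923714 to 7926029 (build not given in the sources used here, as for all coordinates), with peaks of 2179 and 2316 bp in the SIANK libraries. It was followed by regions on chromosome 6 from 127358407 to 127360504 and on chromosome 5 from 172618698 to 172621335. All 10 top-ranked gained regions carried an H3K27ac peak in 1 NC library or, for 1 of them, that on chromosome 6, in both, and the latter also had H4K5ac in a SIANK library. The top lost region was on chromosome 12 from 16340396 to 16342169, with peaks of 1774 and 735 bp in the NC libraries and no peak of either other mark in any library. Of the 10 top-ranked lost regions, 8 carried H3K27ac in a SIANK library, 4 in an NC library and 2 in none, and 3 carried H4K5ac in a SIANK library.

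The gained count of H3K23ac was not the only large one among the ways of pairing its 4 libraries. Libraries NC 1 and SIANK 2 shared 966 regions absent from the other pair, against 82 the other way, and the number 2 libraries shared 668 regions absent from the number 1 libraries, against 174. With each list held to the 10720 longest peaks, the length of the shortest list, H3K23ac gained 507 regions and lost 284, and the number 2 libraries then shared 626 regions absent from the number 1 libraries, against 272, while the crossed pairs gave 412 and 371. Equal lists draw the counts of both sides together by construction. Each call rests on all 4 libraries: without NC 1, NC 2, SIANK 1 and SIANK 2 in turn, the gained counts were 2706, 2673, 4964 and 3941 and the lost counts were 240, 1936, 53 and 746.

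H3K27ac gained 145 regions and lost 10 among 17378 merged regions, far fewer than separated the replicate numbers. Both number 2 libraries shared 7748 regions that were absent from both number 1 libraries, and 107 regions went the other way. The top gained region, on chromosome 7 from 124304712 to 124305734, had peaks of 847 and 1023 bp in the SIANK libraries and carried H3K23ac in all 4 libraries of that mark. The region on chromosome 2 from 144021323 to 144022243 had peaks of 766 and 905 bp and carried H3K23ac in both SIANK libraries and in no NC library. Of the 10 top-ranked gained regions, 8 had H3K23ac in at least 1 NC library, and H4K5ac was found in none of them. The top lost region was on chromosome 11 from 79117616 to 79118586, with peaks of 537 and 971 bp in the NC libraries. With each list held to its 2644 longest peaks, 65 regions were gained and 33 lost. The number 2 libraries then shared 966 regions absent from the number 1 libraries, against 930. Without NC 1, NC 2, SIANK 1 and SIANK 2 in turn, the gained counts were 232, 1937, 3245 and 429 and the lost counts were 1696, 56, 40 and 88, so that without NC 1 more regions were lost than gained.

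H4K5ac gained 213 regions and lost 2 among 1850 merged regions, and 67 regions were found in all 4 of its libraries. The gained share of merged regions was 11.5%, above the 7.34% of H3K23ac. The top gained region, on chromosome 3 from 146384249 to 146386511, had H4K5ac peaks of 1783 and 2263 bp in the SIANK libraries and no peak of the other marks in any library. The next ones, on chromosome 4 from 148150057 to 148152238 and on chromosome 6 from 138071172 to 138072234, likewise lacked H3K23ac and H3K27ac. In all, 4 of the 10 top-ranked gained H4K5ac regions carried no peak of either other mark, and 5 had H3K23ac in all 4 libraries, such as the region on chromosome 17 from 27633137 to 27634223. The lost regions were on chromosome 10 from 86018529 to 86019005 and on chromosome X from 361696 to 362009. With each list held to its 100 longest peaks, 13 regions were gained and 12 lost. Without NC 1, NC 2, SIANK 1 and SIANK 2 in turn, the gained counts were 223, 324, 1398 and 276 and the lost counts were 68, 8, 2 and 8.

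**Figure D2:**
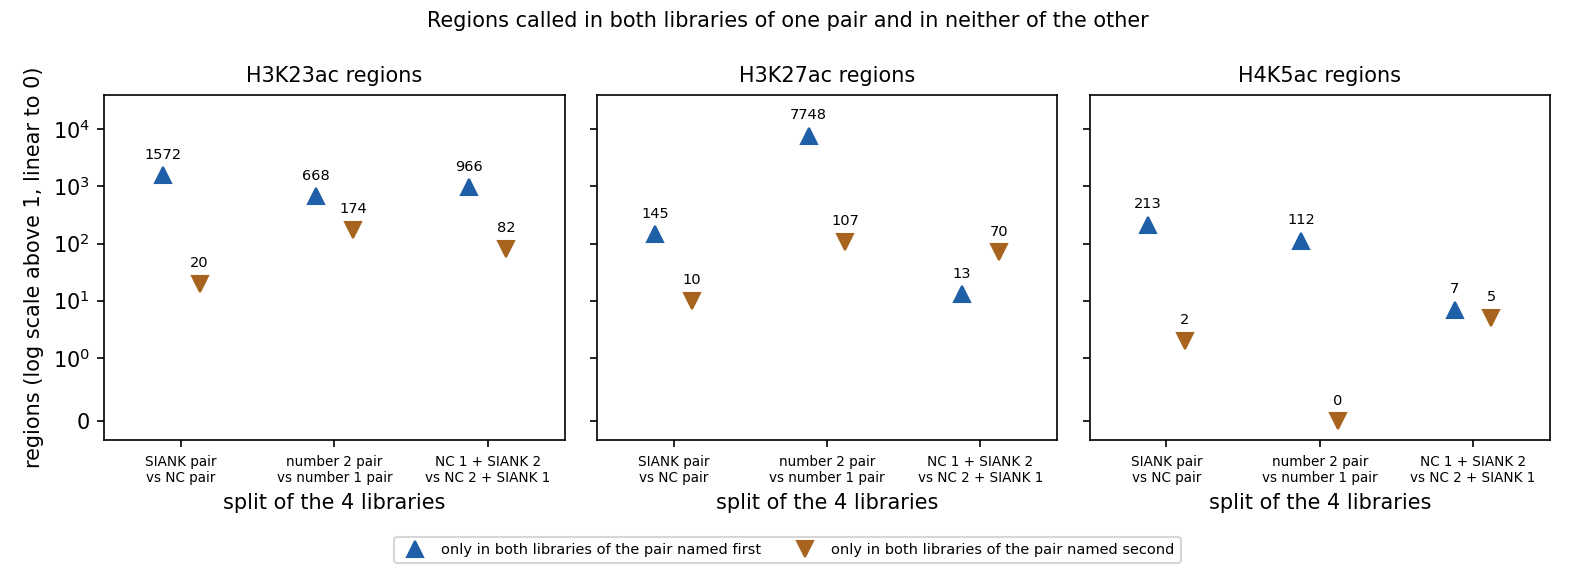
Regions called in both libraries of one pair and in neither of the other pair, for the 3 ways of splitting the 4 libraries of each mark; upward triangles count the pair named first and downward triangles the pair named second, on an axis that is logarithmic above 1. For H3K27ac the largest count, 7748, belongs to the number 2 libraries, while for H3K23ac (1572) and H4K5ac (213) it belongs to the SIANK libraries.

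**Figure D3:**
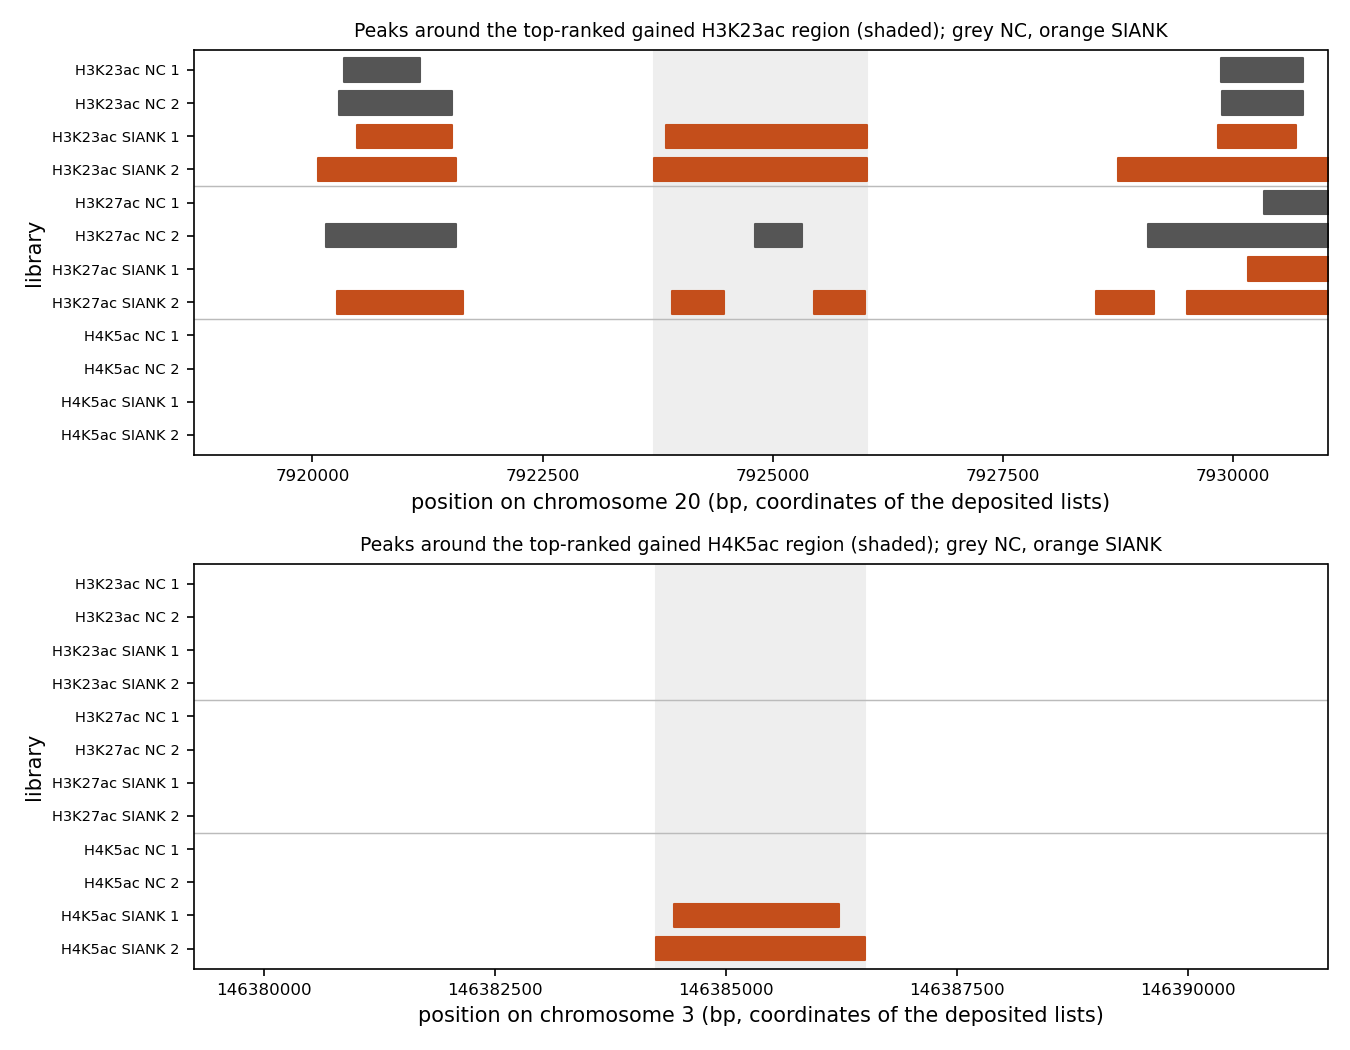
Peaks of all 12 libraries (rows; grey NC, orange SIANK) within 5 kb of the top-ranked gained H3K23ac region on chromosome 20 and the top-ranked gained H4K5ac region on chromosome 3 (shaded), along the position in bp. On chromosome 20 the H3K23ac peaks of 2179 and 2316 bp sit between neighbours found in all 4 H3K23ac libraries, and on chromosome 3 only the 2 SIANK H4K5ac libraries have a peak.

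The regions found in all 4 libraries of a mark included broad domains of H3K23ac and H3K27ac at the same places. For H3K23ac the top-ranked ones were on chromosome 3 from 9542477 to 9550655 (8179 bp) and on chromosome 1 from 221197907 to 221209752 (11846 bp). The top-ranked H3K27ac region, on chromosome 1 from 221199387 to 221209803 (10417 bp), overlapped that same H3K23ac domain. All 5 top-ranked H3K27ac regions carried H3K23ac in all 4 libraries, and all 5 top-ranked H3K23ac regions carried H3K27ac in both conditions. The top-ranked H4K5ac region found in all 4 libraries was shorter, on chromosome 4 from 174244224 to 174246146 (1923 bp), and carried both other marks.

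H3K23ac and H3K27ac largely shared their territory, in both directions, and most H4K5ac regions lay within it. Of the 2214 H3K27ac regions found in all 4 libraries, 1834 (82.8%, exact 95% binomial interval 81.2 to 84.4) overlapped an H3K23ac region found in all 4 libraries, and 99.8% overlapped an H3K23ac region of any library. Taking regions of any library for both marks, 89.9% of the 17378 H3K27ac regions overlapped H3K23ac and 72.1% of the 21414 H3K23ac regions overlapped H3K27ac. Of the 7420 such H3K23ac regions, 24.9% overlapped an H3K27ac region found in all 4 libraries and 99.7% one of any library. Of the 67 such H4K5ac regions, 32 (47.8%, 35.4 to 60.3) overlapped H3K23ac and 10 (14.9%, 7.40 to 25.7) overlapped H3K27ac found in all 4 libraries, and 54 (80.6%, 69.1 to 89.2) overlapped an H3K23ac region of any library. With the upper 50% of each list the 47.8% was 29.0%. The 14.9% was 23.6% without NC library 1 of each mark and 8.33% with equal lists. Shifting regions along their chromosomes gave 0.998% for H3K27ac on H3K23ac and 0.713% for H4K5ac on H3K23ac, and each overlap exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). The shifts treat regions, not libraries, as units. They also move regions anywhere along a chromosome, so they cannot tell shared marking from a shared preference for certain parts of it.

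Over the 3 marks the peaks merged into 23333 regions. H3K23ac and H3K27ac together, without H4K5ac, marked 13925 of them (59.7%), and all 3 marks were found at 1182. H3K23ac stood alone at 5860 regions, H3K27ac at 1714 and H4K5ac at 493.

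**Figure D4:**
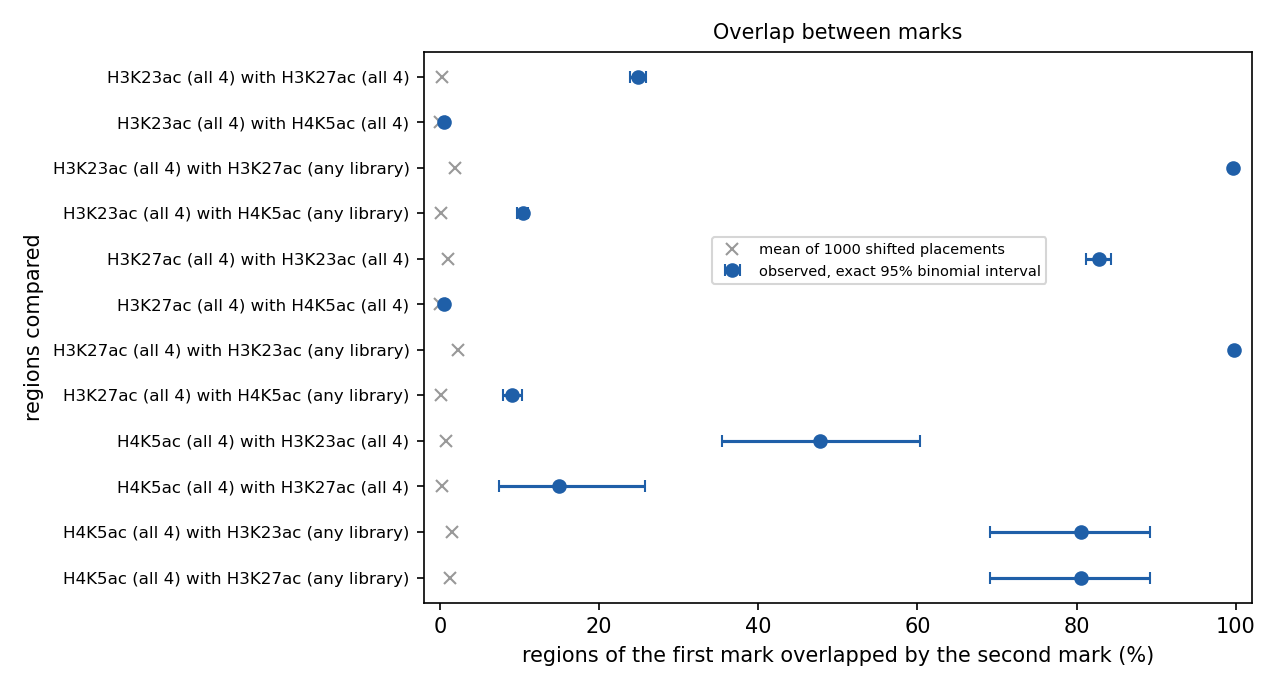
Percent of the regions found in all 4 libraries of one mark that overlap a second mark by at least 1 bp (circles, with exact 95% binomial intervals) and the mean percent after shifting the regions along their chromosomes (crosses). H3K27ac regions overlapped H3K23ac regions found in all 4 libraries in 82.8% of cases against 0.998% after shifts.

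Many regions gained for a mark carried another mark in at least 1 NC library. Of 1554 gained H3K23ac regions in the merged set of the 3 marks, 816 (52.5%) had an H3K27ac peak in at least 1 NC library, 48 had one in both, and 364 had none in any library. Of 213 gained H4K5ac regions, 118 (55.4%) had H3K23ac in at least 1 NC library and 87 in both, and 122 (57.3%) had H3K27ac in at least 1 and 21 in both. Of 144 gained H3K27ac regions, 65 (45.1%) had H3K23ac in at least 1 NC library and 16 in both. Carrying another mark was not particular to gained regions. Overlap with H3K23ac of any library was 89.7% for gained and 89.9% for all H3K27ac regions, and 67.6% and 70.8% for H4K5ac. Overlap with H3K27ac of any library was 76.8% for gained and 72.1% for all H3K23ac regions, and 64.3% and 66.8% for H4K5ac. Shares with a peak in an NC library were not computed for all regions. The NC lists of H3K27ac differed in length, with 2644 and 14034 peaks. Gains of H3K23ac and H3K27ac coincided at 30 regions where independent lists would share 9.59 (odds ratio 3.74, Fisher's exact test over 23333 regions, adjusted p = 1.13e-07). Gains of H3K23ac and H4K5ac coincided at 11 regions against 14.2 (Fisher's exact p = 0.489, adjusted p = 1), and gains of H3K27ac and H4K5ac at 0 against 1.31 (Fisher's exact p = 0.645, adjusted p = 1). No lost region was shared between marks (Fisher's exact p = 1 for each pair). Among regions found in exactly 2 libraries of both marks, 22.7 shared gains of H3K23ac and H3K27ac were expected, and the odds ratio of 1.80 did not pass adjustment (Fisher's exact p = 0.0453, adjusted p = 0.272). With equal lists 2 gains coincided (log2 odds ratio −0.02). The log2 odds ratio of 1.90 turned to −0.21 without NC library 2 and to −0.29 without SIANK library 2 of each mark. Fisher's exact test treats regions, not libraries, as units here.

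For every mark, some pair of lists from different conditions was more similar than a pair from one condition. The mean Jaccard index, the share of merged regions that both lists hold, was 0.574 for H3K23ac libraries of the same condition, 0.541 for the same number and 0.552 for neither. Its pair NC 2 and SIANK 2 (0.574) lay above NC 1 and NC 2 (0.567), and with equal lists the mean for the same condition minus that for the same number went from 0.0333 to −0.00949. For H4K5ac the 3 means were 0.209, 0.162 and 0.167, and its most similar pair was NC 2 and SIANK 1 (0.281). These were the H4K5ac lists closest in length (371 and 468 peaks), and lists of very unequal length cannot reach a high index. With equal lists the H4K5ac difference between same condition and same number went from 0.0465 to 0.0641. For H3K27ac the 3 means were 0.220, 0.600 and 0.222, so its libraries paired by number. The percent of the shorter list also found in the longer one ranged over the pairs of libraries from 71.0 (NC 1 and SIANK 1) to 96.7 (NC 2 and SIANK 2) for H3K23ac, from 86.8 to 94.3 for H3K27ac, and from 49.6 (NC 2 and SIANK 1) to 91.8 (NC 1 and SIANK 2) for H4K5ac.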

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

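Alternatives for peak length at shared regions, overlaps of gained regions and percent overlaps, and the crossed pairing, were chosen after seeing the data. Of 122 values under alternatives, 76 kept direction and side of the threshold (tests), lay within 1.5 times the reported count (counts) or within the spread or interval of the reported value (others). A further 37 moved beyond that, 5 reversed (3 of them also losing their call), 3 passed a threshold missed before and 1 no longer passed. Tests within a mark (smallest p 0.333 or more) or without H4K5ac (0.0556) could not change side. Covered length, merging within 1000 bp and the length threshold changed no call on the number of peaks over the 3 marks. Leaving out H4K5ac lowered the log2 ratio from 1.04 to 0.46 (exact permutation p = 0.389). The chromosome alternative gave no value, since lists held only 1 to 20, X and Y, and promoter and gene-list settings were not run. Depth is unknown.

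With a replicate block, the log2 ratio of peaks over the 3 marks was again 1.04 and that of peak length 0.36. SIANK was higher in 6 of 6 pairs for each. The exact sign-flip p was 0.03125 for each, the smallest that 6 pairs can give. It passed the threshold that the unpaired exact permutation tests missed (p = 0.120 and 0.0648). Both kinds of test take the 3 marks as independent. If the same cells supplied them, these p-values would not hold. The numbers do not establish pairs: presence deviations of same-numbered libraries correlated at 0.02 for H3K23ac, 0.24 for H3K27ac and −0.21 for H4K5ac, with 2 pairs each. Crossing the H4K5ac numbers left the log2 ratio at 1.04 (exact sign-flip p = 0.03125). It could not do otherwise, since both H4K5ac SIANK lists were longer than both NC lists. The counts of 213 gained and 2 lost regions ignore pairs. The H3K27ac numbers were not crossed, although SIANK 1 (4823 peaks) was shorter than NC 2 (14034 peaks) there.

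Gained and lost counts moved most. With the upper 50% of each list, H3K23ac gained 791 and lost 31 and H4K5ac gained 115 and lost 0 regions; fewer peaks entered by construction. With equal lists, which draw gained and lost counts together by construction, they were 507 and 284 for H3K23ac, 65 and 33 for H3K27ac, and 13 and 12 for H4K5ac. Leaving out 1 library asks fewer libraries to agree, which lifts most counts by construction: gained ranged from 2673 to 4964 and lost from 53 to 1936 for H3K23ac, gained from 232 to 3245 and lost from 40 to 1696 for H3K27ac, and gained from 223 to 1398 and lost from 2 to 68 for H4K5ac. The H3K27ac log2 ratio of peaks then ranged from −0.70 to 1.71; removing NC 1 or SIANK 2 turned it negative.

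Equal lists turned the H3K23ac Jaccard difference between same condition and same number from 0.0333 to −0.00949, and the log2 odds ratio of shared H3K23ac and H3K27ac gains from 1.90 to −0.017; among regions of exactly 2 libraries of both marks it was 0.85 and no longer passed (adjusted p = 0.272), and without single libraries it ranged from −0.29 to 1.74, and the cause was not tested. The percent of H3K27ac regions overlapping H3K23ac was 98.3 with equal lists, 76.1 with the upper 50% of lists and 81.7 to 84.7 without single libraries, and that of H4K5ac regions was 29.0 with the upper 50%; the cause was not tested.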

Other observations

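The tests of H3K27ac pairs and containment, of pair products and of H4K5ac regions by number of libraries were chosen after the values they use had been seen. Those of added lists and of flanks were fixed before their results, but the bound under which added lists widen the covered length too little to tell, 2 times, was set after its result had been seen.

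H3K23ac and H3K27ac regions were spread unevenly over the chromosomes. H3K23ac regions found in all 4 libraries were densest on chromosome 10 (5.72 per Mb) and chromosome 12 (5.03 per Mb) and, leaving out Y, sparsest on X, with 0.513 per Mb. Chromosome X held 1.11% of these regions (exact 95% binomial interval 0.880 to 1.37) and 1.13% of the H3K27ac ones (0.732 to 1.66), against 5.76% of the span covered by the lists. Of the 67 such H4K5ac regions 3 lay on X (4.48%, 0.933 to 12.5), an interval that includes the share of span. Among all 1850 H4K5ac regions, 23 lay on X (1.24%, 0.790 to 1.86), which is below the share of span. Of the H3K23ac regions gained in SIANK, 24 (1.53%, 0.981 to 2.26) lay on X. Gained H3K23ac regions lay within 5 kb of a region found in all 4 libraries in 17.9% of cases (281 of 1572), against 18.7% (357 of 1910) of other regions found in exactly 2 libraries. The hypothesis that gains arise at the flanks of constant regions predicted a higher share among gained regions. No such excess was seen (odds ratio 0.947, 95% interval 0.797 to 1.13, Fisher's exact p = 0.538, adjusted p = 1). The hypothesis stays undecided, because the other regions found in exactly 2 libraries may lie at flanks as often. A peak that touches a constant region is also merged into it and cannot be called gained.

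What lies behind the excess of gained over lost regions stays open for all 3 marks. Sequencing depth, signal over background, the calling threshold and a global difference in acetylation between SIANK and NC cells would each lengthen lists in the same way, and the lists hold no value that separates these.

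H3K27ac libraries split by replicate number. With each list held to its 2644 longest peaks they still did, with 966 regions only in number 2 and 930 only in number 1. Lower detection in the number 1 libraries could account for the 7748 regions seen only in number 2. Of the regions in both number 1 libraries, 90.8% (2214 of 2439) were in both number 2 libraries. Averaged over NC 2 and SIANK 2, peaks covered a median of 1241 bp per region where all 4 libraries agreed. Where only number 2 had them, they covered 799.5 bp. A region can hold several peaks of a library. The containment is weak evidence, because far longer lists could hold most of the shorter ones under other causes too. The 107 regions seen only in number 1 argue against lower detection as the whole cause, since NC 1 shared 8.23 times as many regions with SIANK 1 alone as with the longer list SIANK 2 alone (107 against 13, exact 95% interval 4.61 to 16.0), and 10.7 times as many as with NC 2 alone (107 against 10). A preparation shared by number across marks stays open. In H3K23ac the number split also had the largest product of its 2 counts, 1.47 times that of the crossed split (1.11 to 1.94). The H3K23ac condition split had the smallest product, 0.270 times that of the number split (0.169 to 0.433). In H4K5ac the number split rested on 112 and 0 regions. No biological explanation was tested, since the labels do not say what the numbers stand for.

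H4K5ac marked 493 regions outside every H3K23ac and H3K27ac peak, 26.6% of its 1850 regions. Most of the 493, 363 in number, were found in only 1 H4K5ac library, as were 1317 (71.2%) of all 1850 regions. The share outside was 27.6% among regions of 1 library and 27.7% among regions of 2. Of the 1850 regions, 1185 were found in SIANK 2 alone. Chance calls in single libraries are unlikely to be the whole cause, because 36 of the 194 regions found in 3 or 4 H4K5ac libraries (18.6%, 13.3 to 24.8) also lay outside. Whether the lists of the other marks are too short cannot be told: going from the longest list of each to all 8 lists lowered the share outside by 3.57 percentage points, from 30.2% to 26.6%, but widened the covered length by only 24.1%, too little for the large fall that short lists would need to show. Antibody background stays open too, as does a separate H4K5ac compartment as a hypothesis. Among gained H4K5ac regions, 69 of 213 (32.4%, 26.2 to 39.1) lay outside.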
